A study of Mus musculus with 55 samples.

How the data were processed

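RNA of granulocytes, CD4 T helper cells, CD8 T cells and CD4+CD25+ cells (Treg) sorted from mouse bone marrow was made into 55 MARS-seq libraries and sequenced on an Illumina instrument. Per the submitters' processing notes, reads were trimmed with fastp 0.20.0 and aligned with STAR 2.6.0c to GRCm38 (mm10), and DESeq2 1.30.1 was used. How molecular tags were handled and how genes were counted is not given in the sources used here. The deposited values are a signal: each library's reads divided by 1 factor, found from the values themselves, since in every library 100% of values are whole within 0.01 once divided by the value of a single read. Each file holds 15734 features, 5 of them without a symbol, which hold at most 0.0124% of a library's values. Genes carry human-style symbols and human Ensembl IDs, and 15695 of the 15728 distinct symbols equal a mouse symbol in capitals. Coordinates are those of the mouse gene of that name in GRCm38.

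Libraries were grouped by population and stage from their titles, in 16 groups. The late-core granulocytes, whose tissue label reads bone marrow, were grouped by title. Each population was compared between early and normal, late peripheral and normal, late core and late peripheral, and late core and normal marrow, 16 comparisons in all.

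The test fixed before the data were examined was edgeR's quasi-likelihood test with TMM on counts. Because the deposited values are scaled, the test used is limma 3.58.1 (R 4.3.3) with a mean-variance trend and robust variance on log2(value + 4), in 1 fit per population, for genes with a value of at least 10 in as many libraries as the smallest group has. Genes pass at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on this scale, which understates the change of genes with few reads. Tested genes numbered 3808 in granulocytes, 4534 in CD4, 4891 in CD8 and 4793 in Treg. CPM values are recovered reads scaled to the library total. A fold against a group with 0 reads is a bound against a floor of 3 reads over the group, and with 1 to 3 reads the ratio is given with its 95% counting interval. These intervals and floors cover counting error alone, and the p-values measure the spread between libraries, since separate animals are stated for no group and a shared mouse for the late sites.

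Gene lists, 33 in all, were fixed before the data were examined: T cell states (inhibitory receptors, costimulation, cytotoxic effector, naive and memory, Treg effector, T helper polarisation), granule and neutrophil maturation, suppressor cells, inflammation, interferon, antigen presentation, proliferation, stress, metabolism, TGF-beta response and markers of other cell types. Of their 492 members 435 are in the files. Lists with at least 4 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over 360 list tests, of which 167 passed. Lists with fewer members in a comparison were not tested there, which in every comparison left out the MHC class II list and the B cell, erythroid, dendritic cell, natural killer cell, megakaryocyte, basophil, mast cell and eosinophil, and mammary tumour markers. Members are counted by the adjustment over all genes and, after the word or, over the list alone. Differences between T cell populations in the same stage effect were tested for the genes of the inhibitory receptor list with limma in 1 model of the 40 T cell libraries.

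Named genes followed a rule set before the data were examined: for the first 3 comparisons of each population the 6 genes with the smallest p in each direction, with adjusted p under 0.05, an absolute log2 fold change of at least 1 and a mean of at least 20 CPM in the higher group and a symbol that is not a clone or predicted-gene name; up to 4 members of each described list; and fixed checkpoint, cytotoxic and suppressor genes whatever their p. For core against normal marrow the first part was not used. Fixed genes with too few reads to be tested are given as CPM or named as not tested, and lineage and lung genes are given beside these.

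The procedure was tested on data simulated from each gene's mean over a population and its libraries' depth and dispersion, with genes of a mean value of at least 20 changed. Of genes changed 4-fold it recovered 92 to 95% in granulocytes, 77 to 82% in CD4 and 73 to 80% in Treg. In CD8 it was 90% for early, 60% for peripheral and 51% for core against normal and 36% for core against peripheral marrow. Of 2-fold changes it recovered 2 to 41%. All 16 changed lists and 0 unchanged lists were found, but genes were simulated uncorrelated.

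The core and peripheral sites are of the same mouse per the series design, and the number in the file name was taken as the animal. Deviations of paired libraries were checked: 2 of 3 pairs correlated above 0.1 in granulocytes (-0.34 to 0.51), 3 of 3 in CD4 (0.22 to 0.29), 2 of 2 in CD8 (0.11) and 2 of 3 in Treg (0.07 to 0.24).

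Settings also tried were RLE scaling in edgeR 4.0.16, DESeq2 1.42.0 and limma-voom with quality weights on the recovered reads, no filter, a mean of at least 20 CPM, a fit of the compared groups alone, the replicate number or the animal as a block, each library left out, an estimated correlation between genes, and fry. Chosen after the data were seen were the limma settings, the use of edgeR with TMM, the test fixed beforehand, as an alternative to them, offsets of 1 and 16 in place of 4, and the split of libraries by lung transcripts at a summed value of 200, used as a covariate or to leave libraries out. Raw reads were not analysed here. Some genes that the rule selects are not reported here.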

Results

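RNA was measured by MARS-seq in 55 libraries of cells sorted from mouse bone marrow, from healthy animals and from animals with breast cancer metastases in bone. Granulocytes, CD4 T helper cells, CD8 T cells and a CD4+CD25+ population, called Treg here, came from 4 kinds of marrow: normal, early metastatic and, at the late stage, peripheral marrow and the metastatic core. Granulocytes and CD4 cells each had 4 libraries per group and 3 for the core. CD8 cells had 4 normal, 4 early, 2 peripheral and 2 core libraries, and Treg had 4 normal and 3 of each other group. Recovered reads per library were 357058 to 1633022 in granulocytes and 68263 to 876798 in CD4. They were 43224 to 1148806 in CD8 and 90075 to 429903 in Treg.

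The sorted populations differed in their lineage genes. In normal marrow S100A8, a calprotectin subunit abundant in neutrophils, stood at 81400 ± 23300 CPM (mean ± SD) in granulocytes, where CD3E, a chain of the T cell receptor complex, stood at 1.02 ± 0.789. The T cell gene CD3D did not follow CD3E there. It stood at 537 ± 47.9 CPM in normal granulocytes, against 377 ± 134 in normal CD4 libraries. CD4 was at 452 ± 63.3 CPM in CD4 libraries, and CD8A at 134 ± 39.6 in CD8 libraries. In normal Treg libraries FOXP3 (ENSG00000049768 in the files; GRCm38 chromosome X, 7573644 to 7595245, plus strand), the transcription factor that defines regulatory T cells, stood at 4.22 ± 3.67 CPM and IL2RA, which encodes CD25, at 1.53 ± 1.86, against 31.7 ± 6.21 and 6.34 ± 4.51 in normal CD4 libraries. The macrophage complement gene C1QA stood at 9620 ± 550 in Treg and 280 ± 138 in CD4 libraries. In peripheral Treg libraries FOXP3 and IL2RA stood at 14.6 and 4.6 CPM, against 25.9 and 19.3 in CD4. Transcripts of lung, which no sorted population is known to make in quantity, were present in 24 of the 55 libraries. Deposited values of SFTPC, SFTPD, SCGB1A1, MGP, INMT and MFAP4 summed to at most 82.4 in 31 libraries and at least 349 in 24. These 24 were 10 normal, 4 early, 3 peripheral and 7 core libraries.

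**Figure D1:**
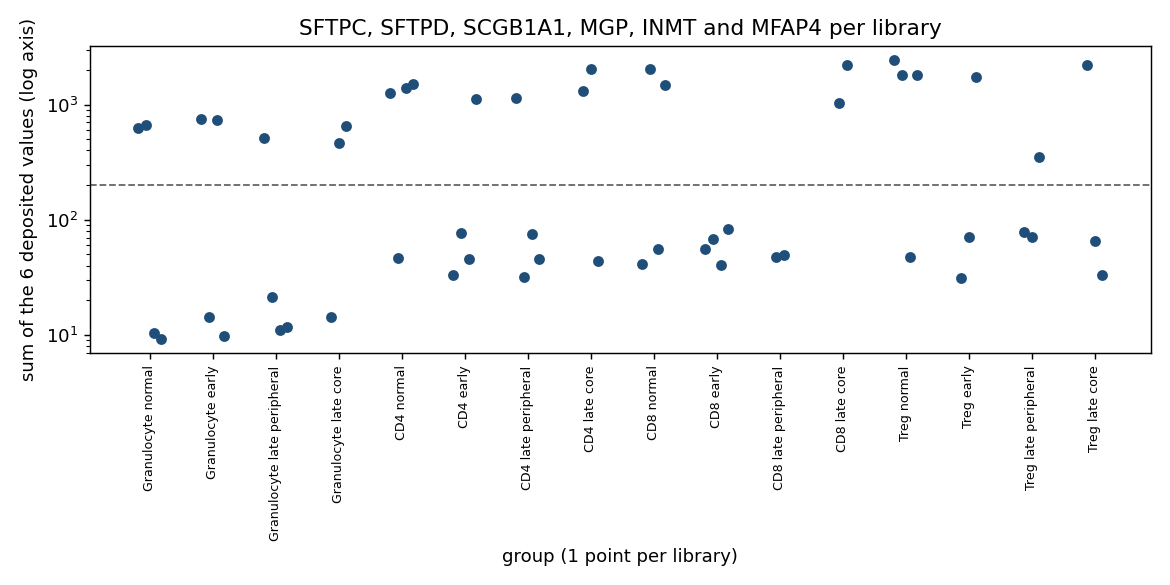
Sum of the deposited values of 6 lung-associated transcripts in each library (log axis), by population and stage, with 1 point per library and a dashed line at 200. Sums are at most 82.4 in 31 libraries and at least 349 in 24.

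**Figure D2:**
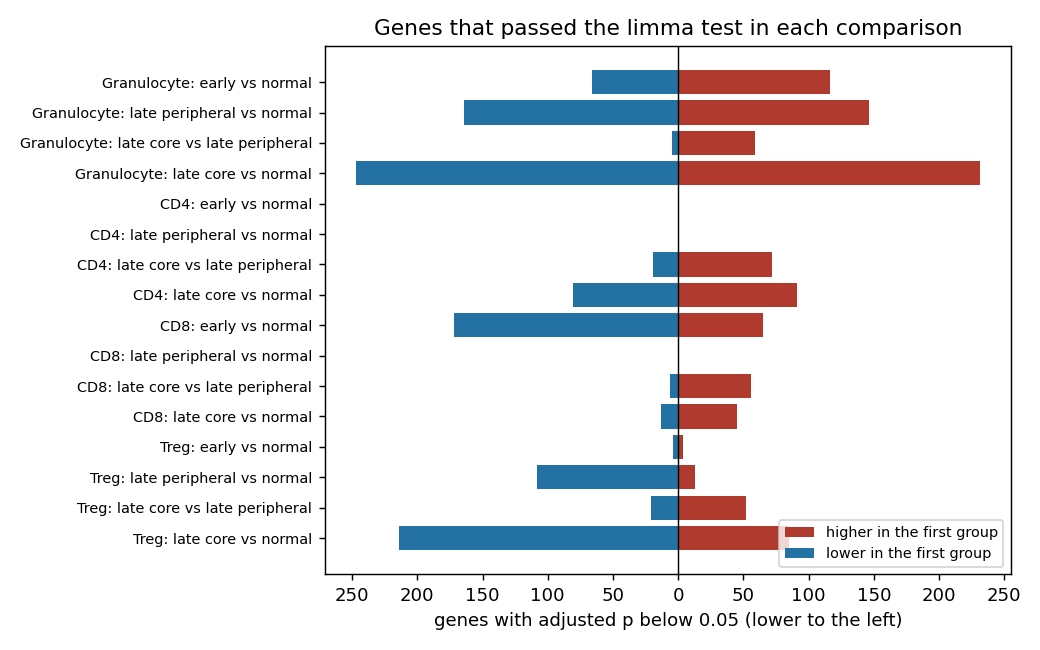
Number of genes with adjusted p below 0.05 in the limma test for each comparison, with genes higher in the first group drawn to the right and genes lower to the left. Granulocytes of the core against normal marrow gave 478 genes, and CD4 early, CD4 peripheral and CD8 peripheral against normal marrow gave 0.

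Granulocytes of early metastatic and normal marrow (n = 4 each) were compared to see what the myeloid cells that can suppress T cells express at the first stage of disease. NOS2 (ENSG00000007171, chromosome 11, 78920787 to 78960254, plus strand), the inducible nitric oxide synthase used by suppressive myeloid cells, rose from 6.1 ± 5.55 to 104 ± 10.8 CPM, a log2 fold change of 3.12 ± 0.46 (SE, adjusted p = 0.0011). The interferon-induced membrane genes IFITM1 and IFITM2 rose by 3.74 ± 0.48 and 2.13 ± 0.22, and IFITM2 reached 4830 ± 695 CPM. FAM20C rose by 3.21 ± 0.33 and TSPO by 2.00 ± 0.21. Higher too were ATP13A2 (2.12 ± 0.23), SEMA6B (2.31 ± 0.27) and MCAM (2.30 ± 0.29). CXCR4, the receptor that holds neutrophils in marrow, fell from 228 ± 41.9 to 76.2 ± 28.2 CPM. TNFSF13B, which encodes the B cell factor BAFF, fell by 2.07 ± 0.28, with ITGB3 at -1.59, RASL11B at -1.83, SLC6A13 at -1.71 and CD3D at -1.72. CD3E stood at only 1.02 ± 0.789 CPM in these normal and 0.654 ± 0.799 in the early granulocytes.

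By gene list, the hypoxia and glycolysis list had 13 tested members, of which the glucose transporter gene SLC2A1 (1.71 ± 0.26), MIF (1.34) and LDHA (0.62) rose and 0 fell, or 4 and 0 adjusted over the list alone (list adjusted p = 0.00199). In the mature neutrophil list IFITM1, IFITM2 and IL1R2 (1.29) rose among 16, also 3 adjusted over the list alone (0.00685). The myeloid-derived suppressor cell list had NOS2, STAT3 (0.74) and the endotoxin co-receptor CD14 (1.13) higher among 17, with 3 higher and 1 lower adjusted over the list alone (0.0474). In the specific granule list CAMP, the cathelicidin gene, fell by 1.02 ± 0.28 and was the only one of 9 to pass, with 2 lower adjusted over the list alone (0.0354). The proliferation list shifted down with 0 of 11 passing, by either adjustment (0.0181). Each of these calls was lost with an estimated correlation: adjusted p = 0.261 for hypoxia and glycolysis, 0.409 for mature neutrophil, 0.429 for suppressor cell, 0.433 for specific granule and 0.477 for proliferation. The calprotectin genes S100A8 (-0.03 ± 0.34) and S100A9 (-0.31), IL1B (0.56) and CXCR2 (0.60) did not pass. ARG1, CD274 and PVR had too few reads to be tested, and NECTIN2 is not among the gene names. Of 3808 genes tested, 116 rose and 66 fell, against 121 and 60 with edgeR and 440 and 445 with limma-voom on the recovered reads. The count was 110, 93, 98 and 99 without normal replicate 1, 2, 3 and 4 in turn and 112 without early replicate 1. The calls for CAMP, IL1R2, CD14 and LDHA ended without at least 5 of the 15 libraries in turn, and those for STAT3 and MIF without normal replicate 3.

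Granulocytes of late peripheral and normal marrow (n = 4 each) were compared. ATP13A2 (2.66 ± 0.23), SEMA6B (2.53 ± 0.27), FAM20C (2.59 ± 0.33), TSPO (1.57 ± 0.21) and NOS2 (3.09 ± 0.46, adjusted p = 0.00078) rose here too. ENTPD3 (2.73 ± 0.29) and ASPRV1 (2.11 ± 0.27) rose as well. CAMP (ENSG00000164047, chromosome 9, 109847379 to 109849617, minus strand) fell from 50200 ± 5090 to 18900 ± 6850 CPM, or by 1.72 ± 0.28. CEBPE fell by 1.69 ± 0.27. Lower too were CXCR4 (-2.02 ± 0.25), TNFSF13B (-2.18), IL1RN (-2.47 ± 0.33), CD3D (-2.15), GAPT (-1.54) and G0S2 (-1.87).

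The specific granule list had CEBPE, CAMP and ORM1 (-1.19) lower and 0 higher among 9, or 4 lower adjusted over the list alone (list adjusted p = 0.00171). In the type I interferon list CMPK2 (-1.88 ± 0.32), RTP4 (-2.10) and IRF7 (-1.51) fell among 8, with 6 lower adjusted over the list alone (0.000248). The mitotic genes BIRC5 (-0.96) and UBE2C (-1.05) fell among the 11 of the proliferation list, with 5 lower adjusted over the list alone (0.00033). These gave adjusted p = 0.292, 0.313 and 0.306 with an estimated correlation. Of the 6 monocyte and macrophage markers tested, C1QA (-1.66), C1QB (-1.16) and C1QC (-1.18) fell, also 3 adjusted over the list alone. The list as a whole did not pass (0.0607). S100A8 (-0.53), S100A9 (-1.43, adjusted p = 0.094), IL1B (-0.73) and CXCR2 (0.99) did not pass. In all, 146 genes rose and 164 fell (edgeR 175 and 156, limma-voom 408 and 445). Without normal replicate 1, 2, 3 or 4 the count was 161, 179, 156 or 178 and without peripheral replicate 2 or 3 it was 172 or 146. The calls for RTP4, IRF7, ORM1, BIRC5 and UBE2C ended without at least 4 of the 15 libraries in turn.

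Core and peripheral marrow came from the same mice, so granulocytes of the metastatic core (n = 3) were compared with those of peripheral marrow (n = 4) to separate the site from the stage. Inflammatory genes rose in the core. CXCL2 (ENSG00000081041, chromosome 5, 90903871 to 90905938, plus strand), a neutrophil-attracting chemokine, went from 58.1 ± 30.5 to 903 ± 86.4 CPM (log2 4.11 ± 0.37, adjusted p = 1.3e-06). IL1B (ENSG00000125538, chromosome 2, 129364570 to 129371139, minus strand), a central inflammatory cytokine, went from 141 ± 50.5 to 1730 ± 837 CPM (3.74 ± 0.42). CCRL2 rose by 4.32 ± 0.36, G0S2 by 3.85 ± 0.30 and CD14 by 3.45 ± 0.32. The complement genes C1QA (3.86 ± 0.35), C1QB (3.00 ± 0.27) and C1QC (3.37 ± 0.27) rose with them. CTSG fell by 2.30 ± 0.39. BEND4 fell too (-1.25 ± 0.30).

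The inflammatory cytokine and chemokine list had 8 of 12 members higher and 0 lower, among them OSM (2.43 ± 0.31) and CXCL3 (2.51 ± 0.40), or 11 adjusted over the list alone (list adjusted p = 2.31e-21, and 0.00221 with an estimated correlation). Immediate early and heat shock genes had BTG2 (2.39 ± 0.26), FOS (2.23), JUNB (1.69) and 1 more higher among 16, or 10 adjusted over the list alone (1.52e-13, and 0.0164 with an estimated correlation). Among monocyte and macrophage markers 4 of 6 rose, also 4 adjusted over the list alone (5.12e-10, and 0.0218 with an estimated correlation). The suppressor cell list had 5 of 17 higher, with TREM1 (1.85 ± 0.22), or 6 adjusted over the list alone (1.05e-08, but adjusted p = 0.0644 with an estimated correlation). In the mature neutrophil list CXCL2, TREM1 and IL1B rose among 16, or 4 adjusted over the list alone (8.96e-05, but adjusted p = 0.278 with an estimated correlation). Endoplasmic reticulum stress genes shifted up with 0 of 10 passing, or 1 adjusted over the list alone (0.0161, but adjusted p = 0.243 with an estimated correlation). THY1 rose by 2.61 ± 0.35. NOS2 (0.53), S100A8 (0.51), S100A9 (1.53) and CXCR2 (-1.34) did not pass. ARG1, the arginase gene of suppressive myeloid cells, stood at 23.1 ± 26.8 CPM in the core and 0.845 ± 1.05 in peripheral marrow and was not tested. In all 59 genes rose and 5 fell (edgeR 58 and 2, limma-voom 68 and 0). Among libraries without lung transcripts, 1 core and 3 peripheral, 154 were higher and 421 lower. Without core replicate 2 the count was 135, of which 79 were higher and 56 lower. The call for BEND4 ended without 4 of the 15 libraries in turn and that for JUNB without core replicate 1 or 3. With the mouse as a block ARHGAP24 (-1.44), AGGF1 (-1.32), DUSP1 (1.23) and APOE (1.97) passed no longer, at adjusted p = 0.054, 0.081, 0.063 and 0.065.

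**Figure D3:**
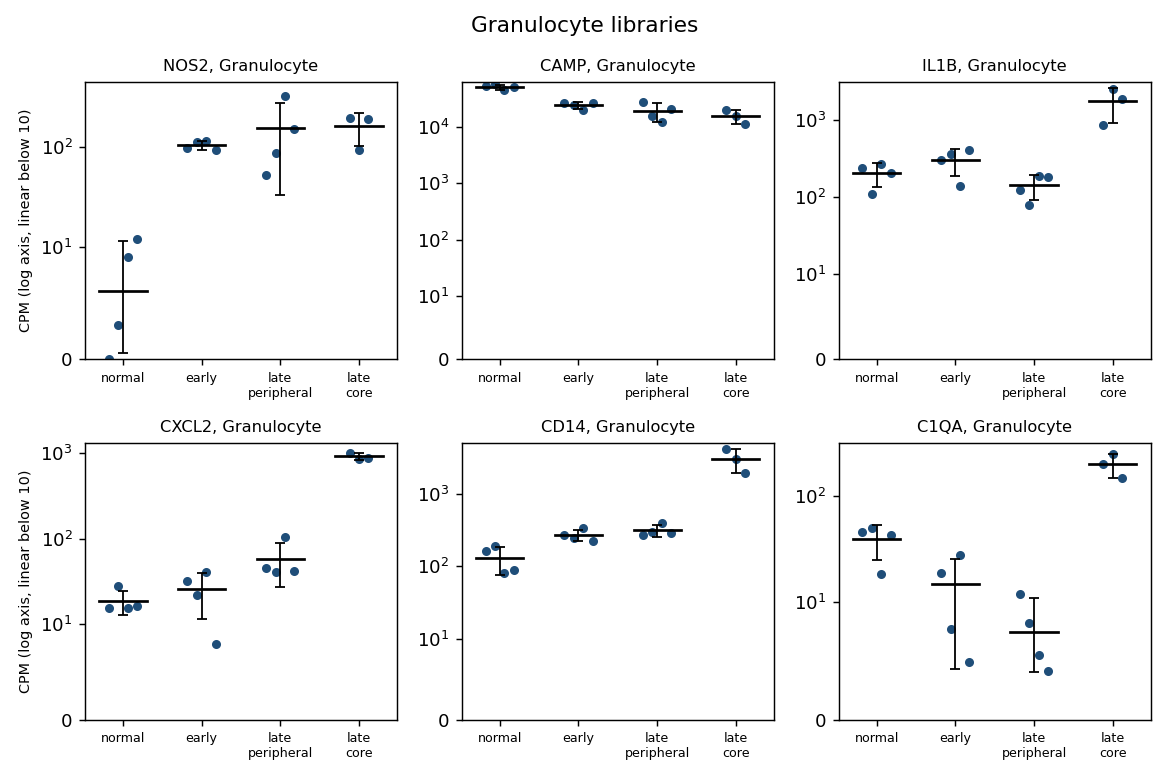
CPM of NOS2, CAMP, IL1B, CXCL2, CD14 and C1QA in granulocyte libraries at each stage (log axis, linear below 10), with 1 point per library, the mean as a line and the SD as error bars. CXCL2 has a mean of 903 in the core, 58.1 in peripheral and 18.8 in normal marrow.

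Granulocytes of the core (n = 3) were also set against normal marrow (n = 4). CXCL2 (5.13 ± 0.37), CD14 (4.49 ± 0.32), NOS2 (3.63 ± 0.49), IL1R2 (3.53 ± 0.37; ENSG00000115590, chromosome 1, 40074079 to 40125231, plus strand), IL1B (3.02 ± 0.42), CEBPB (2.17) and TREM1 (1.86) rose. CEBPE (-1.86 ± 0.29), CAMP (-1.70 ± 0.30) and CD3D (-2.04) fell. Upward went inflammatory cytokines and chemokines (10 of 12 members higher and 1 lower, the same adjusted over the list alone, list adjusted p = 2.02e-09, and 0.0164 with an estimated correlation). So did immediate early (8 of 16, list adjusted p = 6.03e-07), suppressor cell (7 of 17, 8.62e-05), macrophage markers (4 of 6, 1.95e-05) and mature neutrophil (6 of 16 higher and 1 lower, 0.00112) by the preset correlation, with equal numbers adjusted over the list alone. Downward went specific granule (2 of 9, or 4 adjusted over the list alone, 0.0316), type I interferon (2 of 8 by both adjustments, with CMPK2 at -2.49, 0.0131) and proliferation (2 of 11 by both adjustments, with MCM5 at 14.7 against 36.7 CPM, 0.00652). Except for the first, these calls were lost, in this order at adjusted p = 0.0644, 0.174, 0.0863, 0.338, 0.424, 0.477 and 0.405 with an estimated correlation. In total 231 genes rose and 247 fell, while edgeR gave 234 and 164 and limma-voom 325 and 179. The median of all genes was -0.07 here and 0.06 with RLE scaling. The count was 266 and 280 without normal replicate 3 and 4 and 282 without core replicate 3. MCM5 lost its call without normal replicate 3 or core replicate 1 (adjusted p = 0.057 and 0.068).

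CD4 T helper cells of early metastatic and normal marrow (n = 4 each) were compared to ask whether checkpoint receptors are already induced at the early stage. PDCD1, which encodes PD-1, stood at 15.4 ± 11.1 CPM against 22.0 ± 12.2 in normal marrow (-0.28 ± 0.34), CTLA4 at 10.7 ± 8.38 against 14.4 ± 5.76 and TIGIT at 8.75 ± 14.0 against 4.78 ± 4.70. None of the 3 passed, nor did LAG3 (-0.10) or FOXP3 (-0.77). In limma 0 of 4534 genes passed, with 391 at an unadjusted p under 0.05, against 0 in edgeR, 3 in DESeq2 and 1 in limma-voom. Lists of myeloid genes shifted upward with 0 members passing: neutrophil markers (median 1.97 over 7, list adjusted p = 2.78e-05), specific granule (1.67 over 6, 2.52e-06), monocyte and macrophage markers (1.41 over 8, 0.00152). So did mature neutrophil (0.47 over 8, 0.00466), suppressor cell (0.46 over 9, 0.00157), azurophil granule (0.39 over 12, 0.0074) and NADPH oxidase (0.31 over 10, 0.0418). Proliferation (0.46 over 14, 0.00136) and oxidative phosphorylation (0.18 over 15, 0.0154) shifted up. Immediate early genes (-0.57 over 17, 0.00269) and T cell markers (-0.43 over 9, 0.00498) shifted down. Adjusted over the list alone, 3 azurophil, 1 specific granule and 2 proliferation genes were higher, 2 T cell markers lower and 0 in the other lists. All 11 calls were lost with an estimated correlation, at adjusted p = 0.212 for neutrophil markers and specific granule, 0.278 for proliferation, 0.331 for mature neutrophil, suppressor cell and NADPH oxidase. It was 0.349 for both macrophage and T cell markers, 0.412 for azurophil granule, 0.418 for oxidative phosphorylation and 0.445 for immediate early genes. The count was 1 without normal replicate 2 and 3 without early replicate 3.

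In CD4 cells of late peripheral marrow against normal marrow (n = 4 each) PDCD1 stood at 19.6 ± 3.32 CPM (-0.03 ± 0.34), CTLA4 at 29.7 ± 16.5 (0.57) and TIGIT at 15.1 ± 7.52 (0.61). LAG3 stood at 125 ± 107 (-0.88) and FOXP3 at 25.9 ± 21.7 (-0.36), and none of these 5 passed. By limma 0 genes passed and 416 had an unadjusted p under 0.05, against 1 in edgeR, 11 in DESeq2 and 2 in limma-voom. Again granule genes shifted upward, with 0 members passing in any list: azurophil granule (median 0.95 over 12, 6 higher adjusted over the list alone, list adjusted p = 5.47e-07), specific granule (1.77 over 6, 2 higher adjusted over the list alone, 2.75e-06) and neutrophil markers (1.82 over 7, 0 adjusted over the list alone, 6.13e-06). So did proliferation (0.56 over 14, 0 adjusted over the list alone, 0.00112). Immediate early genes (-0.62 over 17, list adjusted p = 2e-04), type I interferon (-0.82 over 5, 0.0011), T cell markers (-0.37 over 9, 0.00377), plasma cell markers (-0.68 over 4, 0.0251) and MHC class I (-0.26 over 7, 0.0317) shifted down. Of these 1, 1, 2, 2 and 0 members were lower adjusted over the list alone. The 9 lists gave, in the order named and with an estimated correlation, adjusted p = 0.174, 0.212, 0.175, 0.274, 0.349, 0.135, 0.338, 0.304 and 0.261. The count was 1 without normal replicate 2 or peripheral replicate 4, 2 without early replicate 3 or 4 and 7 without core replicate 3.

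CD4 cells of the metastatic core (n = 3) against peripheral marrow (n = 4) addressed whether T helper cells next to the tumour carry checkpoint receptors. PDCD1 (ENSG00000188389, chromosome 1, 94038305 to 94052553, minus strand) rose from 19.6 ± 3.32 to 142 ± 28.9 CPM (log2 2.25 ± 0.37, adjusted p = 0.0028). CTLA4 (ENSG00000163599, chromosome 1, 60887000 to 60915832, plus strand) rose from 29.7 ± 16.5 to 173 ± 28.6 CPM (2.20 ± 0.39, adjusted p = 0.0048). BHLHE40 rose by 2.46 ± 0.31 and the NF-kappaB inhibitors NFKBIA and TNFAIP3 by 1.86 ± 0.28 and 2.74 ± 0.50. SMAD7 rose by 2.09 ± 0.31 and VPS37B by 2.30 ± 0.37. TIGIT (ENSG00000181847, chromosome 16, 43648867 to 43664146, minus strand) stood at 46.0 ± 10.8 against 15.1 ± 7.52 CPM and did not pass (1.10 ± 0.47, adjusted p = 0.31). PALM (-1.73 ± 0.32), CLEC12A (-1.63), LYL1 (-1.56), CHDH (-1.79), SRM (-1.10) and MS4A3 (-1.71) fell. LAG3 (-0.30) and FOXP3 (1.18) did not pass, and HAVCR2, CD226, GZMB and IFNG were not tested.

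By list, inhibitory receptors had 3 of 6 higher, with NR4A3 (2.39), or 5 adjusted over the list alone (list adjusted p = 1.34e-06, and 0.0164 with an estimated correlation). Costimulation had TNFRSF9 (2.45 ± 0.44), TNFRSF18 (1.48) and TNFRSF4 (2.38) higher among 6, or 5 adjusted over the list alone (7.23e-07, and 0.0315 with an estimated correlation). Treg effector genes had 4 of 9 higher, or 8 adjusted over the list alone (1.12e-09, and 0.0279 with an estimated correlation). Inflammatory genes had 2 of 7, or 5 adjusted over the list alone (2.16e-07, and 0.0164 with an estimated correlation). Core replicate 3 stood apart, with IL1B at 530 and CXCL2 at 405 CPM against 35.6 to 97.1 and 19.8 to 29.2 in the other 2, and without it the list passed (1.56e-05). Naive and memory genes had CCR7 (2.47), KLF2 (1.46) and S1PR1 (2.07) higher among 10, or 5 adjusted over the list alone (0.000248). Immediate early genes had 5 of 17, or 12 adjusted over the list alone (2.6e-14), and TGF-beta response genes 2 of 8, or 4 (0.0022). T cell markers had 4 of 9, with CD3G (1.59), or 8 adjusted over the list alone (median 1.21, 1.61e-09). Azurophil granule genes had 3 of 12 lower, or 7 adjusted over the list alone (1.02e-05). Neutrophil markers (median -0.65, 1 lower adjusted over the list alone, 0.0272) and plasma cell markers (-0.74, 0 adjusted over the list alone, 0.0287) shifted down. Stromal markers shifted up (1.04, 0 adjusted over the list alone, 0.0154). In these 3 lists 0 members passed. The neutrophil marker list lost its call with the lung covariate (median 0.37, adjusted p = 0.987) and passed upward without lung libraries (0.73, 0.036), from 1 core library. The calls were lost with an estimated correlation at adjusted p = 0.101 for naive and memory, 0.0868 for immediate early, 0.0768 for TGF-beta and 0.0833 for T cell genes. It was 0.228 for azurophil, 0.455 for neutrophil, 0.306 for plasma cell and 0.338 for stromal genes. Lung transcripts were in 2 of 3 core and 1 of 4 peripheral libraries, and among libraries without them 0 genes passed, from 1 core library. In all 72 genes rose and 19 fell (edgeR 80 and 19, limma-voom 131 and 38). The count was 59, 198, 50 and 55 without peripheral replicate 1, 2, 3 and 4 and 51 and 20 without core replicate 1 and 2. The calls of PDCD1, CTLA4, BHLHE40, NFKBIA, TNFAIP3, SMAD7, VPS37B, PALM, TNFRSF9, TNFRSF18 and CD3G alone among those named held without each library in turn. With the mouse as a block LRRC32 (1.80), JUNB (2.55), CD2 (1.61) and PRTN3 (-2.08) passed no longer, at adjusted p = 0.07, 0.08, 0.063 and 0.083, nor did the neutrophil marker list (adjusted p = 0.0514).

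**Figure D4:**
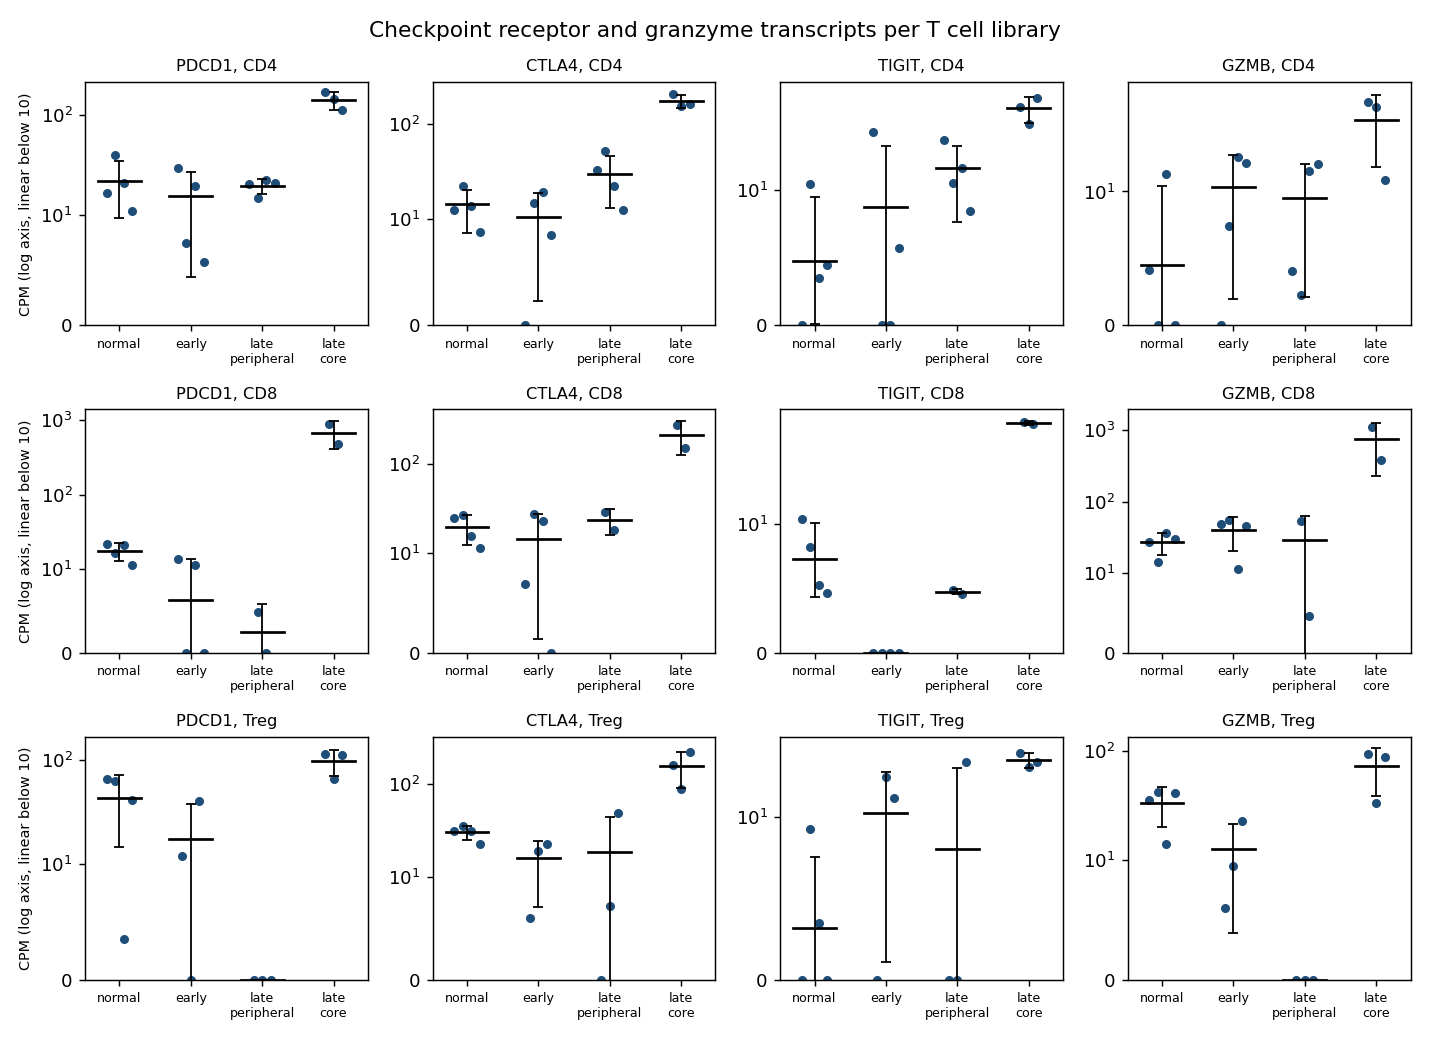
CPM of PDCD1, CTLA4, TIGIT and GZMB in CD4, CD8 and Treg libraries at each stage (log axis, linear below 10), with 1 point per library, the mean as a line and the SD as error bars. PDCD1 has a mean of 142 in CD4, 673 in CD8 and 98.2 in Treg libraries of the core.

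Against normal marrow the CD4 cells of the core had higher CTLA4 (2.77 ± 0.39, adjusted p = 0.00032), PDCD1 (2.22 ± 0.37), TNFAIP3 (3.10 ± 0.50), TNFRSF9 (2.41 ± 0.44) and CCR7 (2.61). TIGIT passed here (1.71 ± 0.47, adjusted p = 0.042) but not without 8 of the 15 libraries in turn. CCR7 and MZB1 lost their calls without core replicate 2 (adjusted p = 0.052 and 0.097) and TXNDC5 without 7 libraries in turn (up to 0.12). LAG3 (-1.18) and FOXP3 (0.82) did not pass. Inhibitory receptors had 3 of 6 higher, with 4 higher and 1 lower adjusted over the list alone (list adjusted p = 0.000311, and 0.0393 with an estimated correlation). Inflammatory genes had 3 of 7, or 4 adjusted over the list alone (4.34e-05, and 0.0279 with an estimated correlation). Also upward, but lost with an estimated correlation, were Treg effector (list adjusted p = 9.53e-07, then adjusted p = 0.0709), costimulation (0.00118, then 0.119), naive and memory (0.000419, then 0.105). So were immediate early (1.08e-05, then 0.3), TGF-beta response (0.0074, then 0.101), T cell markers (0.000396, then 0.278), hypoxia (0.0176, then 0.335) and specific granule genes (0.0171, then 0.477). In these 8 lists 3, 3, 3, 3, 4, 2, 0 and 0 members passed, and 7, 4, 4, 4, 4, 6, 4 and 1 adjusted over the list alone. Plasma cell markers had MZB1 (-1.78 ± 0.37) and TXNDC5 (-1.21) lower among 4, or 3 adjusted over the list alone (0.00035, adjusted p = 0.112 with an estimated correlation). In all 91 genes rose and 81 fell (edgeR 101 and 87, limma-voom 193 and 180). The count was 88, 103, 86 and 113 without normal replicate 1, 2, 3 and 4, 264 without peripheral replicate 2 and 34 without core replicate 2. It was 0 among libraries without lung transcripts, 1 against 1.

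CD8 cells of early metastatic and normal marrow (n = 4 each) were compared to see how cytotoxic T cells differ at the early stage. DAPL1 (-3.14 ± 0.41) fell, as did S1PR1 (-2.64 ± 0.35, adjusted p = 7e-04), the receptor for exit into blood, TCF7 (-2.15 ± 0.38) and DGKA (-2.12 ± 0.30). With the lung transcript split as a covariate TCF7 lost its call (adjusted p = 0.11), and among libraries without these transcripts, 4 early and 2 normal, all 4 did (0.13, 0.13, 0.25 and 0.2). TDRP fell from 184 to 3 reads, a ratio of 0.0625 (95% counting interval 0.0128 to 0.186). The ribosomal protein genes RPS23 and RPS16 fell by 1.85 ± 0.24 and 1.71 ± 0.24. NAPSA (1.77 ± 0.29), NUCB2 (2.34 ± 0.42), KCTD12 (2.09), MAPKAPK2 (1.23), STXBP2 (1.36) and GPX1 (1.26) rose. So did FPR2 (2.15), SLPI (1.76), TYROBP (1.60) and NCF1 (1.58), genes of myeloid cells. With the covariate no gene that rose kept its call. Early replicate 3 stood apart, with S100A8 at 68600 CPM against 4990 to 6690 and NOS2 at 148 against 0 to 18.4. Without it TYROBP did not pass (adjusted p = 0.078).

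Naive and memory genes had 5 of 10 lower, or 7 adjusted over the list alone (list adjusted p = 5.55e-06). Cytotoxic effector genes had 5 of 17 lower, with CTSW (-1.28), NKG7 (-1.11) and CCL5 (-1.33), or 7 adjusted over the list alone (0.0013). T cell markers had 5 of 9 lower, with CD3G (-1.83), CD3D (-1.39) and CD2 (-1.44), or 8 adjusted over the list alone (3.29e-07). Immediate early genes had 1 of 17 lower, or 3 adjusted over the list alone (0.00962), and stromal markers 1 of 10, or 2 (0.0163). Upward went mature neutrophil genes (2 of 10 by both adjustments, 1.14e-06). Suppressor cell (2 of 11, or 7 adjusted over the list alone, 4.03e-06) and specific granule genes (1 of 7, or 5, 7.34e-06) followed. So did NADPH oxidase genes (3 of 10, or 5, 0.0074). Neutrophil (median 1.83, 0 of 9 by both, 0.000168) and macrophage markers (median 1.02, 0 of 9, or 1, 0.00776) did too. The 11 lists, in the order named, gave adjusted p = 0.137, 0.306, 0.105, 0.547, 0.353, 0.218, 0.0931, 0.271, 0.3, 0.331 and 0.451 with an estimated correlation. Among receptors, PDCD1 (3 against 25 reads, ratio 0.46, 0.0889 to 1.51), CTLA4 (-0.44), LAG3 (1.18), GZMB (0.21) and IFNG (-0.48) did not pass. TIGIT had 0 reads in the early libraries and 11 in normal ones. In total 65 genes rose and 172 fell (edgeR 57 and 139, limma-voom 146 and 154). The median of all genes was -0.10 against 0.02 with RLE scaling. Lung transcripts were in 2 of 4 normal and 0 of 4 early libraries. With that split as a covariate the immediate early list lost its call (median -0.03, adjusted p = 0.55). Then 8 genes passed, all lower, and 0 among libraries without lung transcripts. The NADPH oxidase list lost its call without early replicate 3 (0.0597). The count was 94, 75 and 59 without normal replicate 2, 3 and 4. The calls for GPX1, CTSW, FPR2 and SLPI ended without normal replicate 4. They ended for NKG7 and CCL5 without normal replicate 3 or 4, and for NCF1 and TYROBP without 4 and 6 of the 12 libraries in turn.

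CD8 cells of late peripheral (n = 2) and normal marrow (n = 4) were compared. PDCD1 had 1 read over both peripheral libraries and 25 over the normal ones (ratio 0.0918, 0.00224 to 0.561). TIGIT had 3 and 11, and CTLA4 stood at 23.8 ± 7.62 against 19.7 ± 7.24 CPM. These did not pass, nor did LAG3, GZMB or IFNG. In limma 0 of 4891 genes passed, with 170 at an unadjusted p under 0.05, against 0 in edgeR and DESeq2 and 5 in limma-voom. Immediate early genes (median -0.76 over 17, list adjusted p = 6.39e-07), cytotoxic effector (-0.68 over 17, 2.78e-05), proliferation (-0.45 over 14, 0.0032) and stromal markers (-0.95 over 10, 0.00685) shifted down. So did T helper polarisation (-0.77 over 4, 0.00976), T cell markers (-0.44 over 9, 0.0181) and inhibitory receptors (-0.25 over 12, 0.0394). Upward went specific granule (0.73 over 7, 0.00345), suppressor cell (0.47 over 11, 0.0147) and neutrophil markers (0.68 over 9, 0.0298). In all 10 lists 0 members passed. Lung transcripts were in 2 of 4 normal and 0 of 2 peripheral libraries. With that split as a covariate the specific granule, neutrophil and stromal lists lost their calls (medians 0.07, -0.15 and 0.06, adjusted p = 0.634, 0.286 and 0.993). Adjusted over the list alone 2 cytotoxic genes and 1 inhibitory receptor were lower and 0 genes passed in the other lists. The 10 lists, in the order named, gave adjusted p = 0.292, 0.218, 0.482, 0.313, 0.135, 0.376, 0.311, 0.413, 0.306 and 0.547 with an estimated correlation.

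CD8 cells of the metastatic core and of peripheral marrow (n = 2 each) were compared. PDCD1 had 1103 reads in the core and 1 in peripheral marrow, a ratio of 396 (71 to 15700). Its mean was 673 ± 272 against 2.43 ± 3.44 CPM (limma adjusted p = 2.2e-05). GZMB (ENSG00000100453, chromosome 14, 56258838 to 56262260, minus strand), a cytotoxic granule protease, rose from 29.0 ± 34.5 to 741 ± 509 CPM (4.43 ± 0.62). The checkpoint receptor genes HAVCR2 (ENSG00000135077, chromosome 11, 46454935 to 46481255, plus strand; 148 against 1 read, ratio 53.2, 9.39 to 2110), TIGIT (133 against 3 reads, ratio 15.9, 5.33 to 78.2), LAG3 (ENSG00000089692, chromosome 6, 124904361 to 124911705, minus strand; 3.10 ± 0.65) and CTLA4 (2.69 ± 0.57) rose as well. S100A4 (4.28 ± 0.45), NRGN (4.73 ± 0.52), IER5L (3.86 ± 0.51) and RGS16 (4.05 ± 0.54) rose. CXXC5 (-2.39), SMIM5 (-2.75) and CD7 (-2.02) fell. IFNG had 226 reads in the core and 2 in peripheral marrow (ratio 40.6, 11.1 to 337) and did not pass (adjusted p = 0.055). FOXP3 and CD226 were not tested.

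Inhibitory receptors had 7 of 12 higher, or 9 adjusted over the list alone (list adjusted p = 2.48e-12, and 0.0164 with an estimated correlation). Inflammatory genes had 1 of 8 higher, or 6 adjusted over the list alone (1.11e-06, and 0.0218 with an estimated correlation). Costimulation had TNFRSF9 (3.50 ± 0.51) higher among 7, or 4 adjusted over the list alone (0.000263). Cytotoxic effector genes had 3 of 17 higher, or 10 adjusted over the list alone (2.87e-10), and Treg effector genes 2 of 10, or 6 (5.24e-05). Immediate early genes had 6 of 17 higher, with JUNB (2.49) and DUSP1 (2.96), or 15 adjusted over the list alone (1.45e-15). Hypoxia and glycolysis genes had TPI1 (2.07) higher among 9, or 4 adjusted over the list alone (5.2e-05). TGF-beta response genes had ID2 (2.33) higher among 9, or 3 (0.015). T cell markers (median 0.48, 2 of 9 adjusted over the list alone, 0.0212) and stromal markers (2.01, 5 of 10 adjusted over the list alone, 0.00112) shifted up, with 0 members passing. Downward went neutrophil markers (median -2.48 over 9, 2.52e-05), specific granule (-1.81 over 7, 0.00136) and naive and memory genes (-0.78 over 10, 0.00233). So did azurophil granule (-1.46 over 11, where NKG7 alone passed, upward at 1.42, 0.0297) and plasma cell genes (-0.65 over 4, 0.0473). In these 5 lists 0, 0, 2, 0 and 1 were lower adjusted over the list alone. The azurophil and specific granule lists lost their calls with the lung covariate (medians -0.37 and 0.33, adjusted p = 0.661 and 0.402). The calls of the 13 lists after the first 2 were lost with an estimated correlation, at adjusted p = 0.146, 0.0837, 0.113, 0.105, 0.105, 0.3, 0.388, 0.261, 0.295, 0.376, 0.3, 0.477 and 0.335 in the order named. In all 56 genes rose and 6 fell, against 110 and 45 in edgeR and 32 and 8 in limma-voom. Both core and 0 peripheral libraries held lung transcripts, so that split and the site cannot be told apart within these 4 libraries. With it as a covariate over all CD8 libraries 10 genes passed, PDCD1 and GZMB among them (adjusted p = 0.0035 and 0.035), but not TIGIT, HAVCR2, LAG3 or CTLA4 (0.15, 0.14, 0.56 and 0.42). The count was 108 without normal replicate 2 or early replicate 3, 17 without peripheral replicate 1, and 7 and 28 without core replicate 1 and 2. Without each library in turn PDCD1, S100A4, NRGN, IER5L and RGS16 alone among those named kept their calls. TIGIT lost its call without any 1 of the 4. With the mouse as a block TYROBP (-2.49), SLPI (-2.24), KLRC1 (120 against 2 reads) and CXCL1 (495 against 3 reads) passed no longer, at adjusted p = 0.064, 0.064, 0.057 and 0.057.

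Against normal marrow the CD8 cells of the core had higher PDCD1 (4.52 ± 0.46, adjusted p = 2.8e-05), GZMB (4.17 ± 0.53), TNFRSF9 (3.29 ± 0.44), CTLA4 (2.85 ± 0.49), TIGIT (2.20 ± 0.44, adjusted p = 0.015), LAG3 (2.62 ± 0.56) and HAVCR2 (148 against 1 read, ratio 122, 21.6 to 4850). IFNG did not pass (1.94, adjusted p = 0.2). Inhibitory receptors had 6 of 12 higher, or 7 adjusted over the list alone (list adjusted p = 5.37e-13, and 0.0164 with an estimated correlation). Inflammatory genes had 1 of 8 higher, or 5 adjusted over the list alone (1.11e-06, and 0.0218 with an estimated correlation). Other calls were lost with an estimated correlation: upward immediate early (list adjusted p = 1.89e-11, then adjusted p = 0.175), cytotoxic effector (6.52e-06, then 0.186), costimulation (2.15e-05, then 0.105), Treg effector (2.78e-05, then 0.105). So were hypoxia (4.43e-05, then 0.105), TGF-beta response (0.00345, then 0.233) and stromal genes (0.0232, then 0.376). Lost downward were naive and memory (0.000397, then 0.243), neutrophil (0.000501, then 0.349), azurophil (0.00098, then 0.309) and plasma cell genes (0.00683, then 0.234). In these 11 lists 3, 2, 1, 2, 1, 1, 0, 0, 0, 0 and 1 members passed in the list's direction, and 9, 10, 4, 5, 2, 2, 0, 3, 0, 0 and 1 adjusted over the list alone. In all 45 genes rose and 13 fell (edgeR 80 and 36, limma-voom 162 and 82). The count was 37 and 32 without normal replicate 3 and 4, 11 and 31 without core replicate 1 and 2, and 34 with the lung transcript split as a covariate. Without core replicate 1 CTLA4, TIGIT, LAG3, HAVCR2 and TNFRSF9 lost their calls (adjusted p = 0.3, 0.35, 0.6, 0.15 and 0.079), TIGIT also without 2 other libraries in turn and LAG3 without 5, while PDCD1 and GZMB held.

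Treg libraries of early metastatic (n = 3) and normal marrow (n = 4) were compared. S100A8 rose from 4190 ± 1140 to 19000 ± 2290 CPM (log2 2.21 ± 0.35, adjusted p = 0.018), with the neutrophil genes LRG1 (2.63 ± 0.36), NCF1 (1.58 ± 0.28) and ALOX5AP (1.35 ± 0.27). The antibody joining chain gene JCHAIN fell from 1260 ± 295 to 102 ± 73.5 CPM (-3.68 ± 0.48). ALAS2 fell from 135 to 2 reads (ratio 0.0369, 0.00442 to 0.136), CD82 by 1.22 ± 0.22 and ITGAD by 2.00 ± 0.38. PDCD1 (-0.87), CTLA4 (-0.59), LAG3 (0.54) and GZMB (-0.81) did not pass. TIGIT, FOXP3, HAVCR2, CD226 and IFNG were not tested in Treg libraries. Specific granule genes (median 1.71 over 8, 0 passing, 4 higher adjusted over the list alone, list adjusted p = 1.89e-11), neutrophil markers (1.02, 1 of 9, or 3 adjusted over the list alone, 3.94e-08) and mature neutrophil genes (0.60, 0 of 11, or 1 adjusted over the list alone, 0.000131) shifted up. So did suppressor cell (0.26, 2 of 13, or 3 adjusted over the list alone, 0.00218), NADPH oxidase (0.58, 1 of 10, with 3 higher and 1 lower adjusted over the list alone, 0.0097) and proliferation genes (0.30, 0 of 16 by both, 0.000581). Plasma cell markers (-1.82, 1 of 6, or 5 adjusted over the list alone, 9.1e-08), immediate early genes (-0.90, 0 of 16 by both, 0.0102) and stromal markers (-1.01, 0 of 10 by both, 0.0326) shifted down. Lung transcripts were in 3 of 4 normal and 1 of 3 early libraries, and without them, with 1 normal library left, the last 2 lists lost their calls (medians 0.28 and 0.11, adjusted p = 0.147 and 0.71). The 9 lists, in the order named, gave adjusted p = 0.101, 0.179, 0.186, 0.335, 0.3, 0.338, 0.0536, 0.602 and 0.489 with an estimated correlation. In all 4 genes rose and 4 fell of 4793 (edgeR 6 and 4, limma-voom 30 and 34). The count was 2, 2 and 5 without normal replicate 1, 2 and 4, and 2 and 1 without early replicate 1 and 2. It was 13 and 25 without peripheral replicate 2 and 3, and 14 and 15 without core replicate 1 and 3. JCHAIN alone kept its call without each library in turn.

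Treg libraries of late peripheral (n = 3) and normal marrow (n = 4) were compared. LRG1 (2.12 ± 0.36), ALOX5AP (1.28), TMEM40 (1.87), NHP2 (1.22) and SMN1 (1.41) rose, and NCF1 went from 273 ± 94.1 to 648 ± 59.6 CPM. CD74, the invariant chain of MHC class II, fell from 10300 ± 1400 to 2700 ± 1130 CPM (-1.97 ± 0.24, adjusted p = 0.00054). SDC3 (-2.28 ± 0.30), CD82 (-1.59), ITGAD (-2.52), the ferritin gene FTH1 (-1.14) and the macrophage genes CD5L (-2.36 ± 0.37) and ADGRE1 (-1.94) fell with it. Peripheral replicate 3 stood apart, with C1QA at 1870 CPM against 8350 and 7920 and CD3D at 555 against 69 and 35.7. GZMB had 0 reads in peripheral and 42 in normal libraries, at least 5.47-fold lower (adjusted p = 0.049). PDCD1 had 0 and 56, at least 7.29-fold lower without passing (adjusted p = 0.077). CTLA4 (-0.73) and LAG3 (0.76) did not pass. Type I interferon genes had 2 of 7 lower, with IRF7 (-1.66 ± 0.28), or 4 adjusted over the list alone (list adjusted p = 0.0126). Plasma cell markers had 3 of 6 lower, with JCHAIN (-3.11), or 6 adjusted over the list alone (3.75e-06). Macrophage markers had 1 of 11, or 3 (0.0338). Immediate early (median -1.09, 0 of 16 by both, 0.000397) and endoplasmic reticulum stress genes (-0.53, 0 of 11, or 1 adjusted over the list alone, 0.00716) shifted down. Without lung libraries the immediate early list lost its call (median -0.01, adjusted p = 0.916). Upward went specific granule genes (1 of 8, or 3 adjusted over the list alone, 1.09e-06) and neutrophil markers (1 of 9, or 2, 1.89e-05). Mature neutrophil (0 of 11, or 4, 0.000442) and azurophil granule genes (0 of 12, or 1, 0.00157) followed. So did oxidative phosphorylation (0 of 15 by both, 0.00671), proliferation (0 of 16 by both, 0.039) and hypoxia genes (1 of 10 by both, 0.0485). Suppressor cell genes (1 of 13, or 2, 0.0485) did too, with a median of -0.10 against an upward test. The 13 lists, in the order named, gave adjusted p = 0.261, 0.0833, 0.559, 0.488, 0.306, 0.218, 0.281, 0.22, 0.362, 0.357, 0.547, 0.468 and 0.511 with an estimated correlation. In all 13 genes rose and 108 fell against 18 and 57 in edgeR and 182 and 133 in limma-voom. The median of all genes was -0.13 against -0.001 with RLE scaling. The count was 32, 24, 187 and 28 without normal replicate 1, 2, 3 and 4 and 22 and 183 without peripheral replicate 2 and 3. LRG1, CD74, SDC3, CD82, ITGAD, CD5L, FTH1, IRF7 and JCHAIN alone among those named kept their calls without each library in turn. Among libraries without lung transcripts, 2 peripheral and 1 normal, 6 genes passed.

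Treg libraries of the core and of peripheral marrow (n = 3 each) were compared. PDCD1 had 54 reads in the core and 0 in peripheral marrow, at least 17-fold higher (adjusted p = 0.013), and GZMB 42 and 0, at least 13.2-fold higher (adjusted p = 0.012). CTLA4 rose from 18.5 ± 26.0 to 156 ± 65.8 CPM (2.57 ± 0.48, adjusted p = 0.0092). Peripheral replicate 3 stood apart, with CTLA4 at 48.2 CPM against 0 and 7.14 and CD3E at 121 against 41.4 and 7.14. The costimulatory receptor genes TNFRSF4 (2.95 ± 0.41), which encodes OX40, TNFRSF9 (3.07 ± 0.49) and TNFRSF18 (3.25 ± 0.67) rose. So did TNFAIP3 (3.05 ± 0.43), IRF7 (2.25 ± 0.30), VPS37B (2.17), LIME1 (2.22) and PLK3 (49 against 3 reads, ratio 15.4, 4.98 to 77.3). ETFB (-1.92 ± 0.33) and UQCR11 (-1.36 ± 0.24), DTYMK (-1.85) and CD79B (-1.57) fell, as did TMEM40 and KCNK12, each with 1 read in the core. LAG3 (-0.08) did not pass.

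Costimulation had 4 of 6 higher, or 6 adjusted over the list alone (list adjusted p = 5.69e-09, and 0.0476 with an estimated correlation). Treg effector genes had 3 of 7 higher, or 5 adjusted over the list alone (2.02e-06, and 0.027 with an estimated correlation). Inflammatory genes had 5 of 12 higher, or 9 adjusted over the list alone (3.34e-11). Core replicate 3 stood apart, with IL1B at 89.3 CPM against 1510 and 799 in the other 2 (40.2 to 50 in peripheral marrow) and CD14 at 197 against 2640 and 1290 (137 to 189). Inhibitory receptors had 2 of 5 higher, or 3 adjusted over the list alone (0.000488). Immediate early genes had 2 of 16 higher, or 4 adjusted over the list alone (1.61e-09). T cell markers had CD2 (3.29) among 9, or 5 (9.4e-07). Naive and memory genes had KLF2 (1.91) higher among 9, or 4 (0.00125), and type I interferon genes IRF7 and ZBP1 (1.94) among 7, or 3 (0.0227). Mature neutrophil genes had CXCL2 (2.89) higher among 11, or 5 (0.00979). TGF-beta response genes had 0 of 8, or 3 (0.00652), and MHC class I 0 of 7 by both (0.00754). Azurophil granule (median -1.58 over 12, 5.69e-09), neutrophil markers (-1.24 over 9, 3.75e-06), specific granule (-1.13 over 8, 0.000638), proliferation (-0.87 over 16, 0.000112) and oxidative phosphorylation (-0.39 over 15, 0.00427) shifted down. In these 5 lists 0 members passed, and 7, 7, 5, 2 and 0 were lower adjusted over the list alone. These 14 lists, in the order named, gave adjusted p = 0.0833, 0.175, 0.278, 0.22, 0.306, 0.29, 0.331, 0.261, 0.331, 0.135, 0.261, 0.342, 0.304 and 0.343 with an estimated correlation. In all 52 genes rose and 21 fell (edgeR 30 and 9, limma-voom 47 and 7). With the mouse as a block 216 passed. The count was 39 and 43 without normal replicate 2 and 4, 20, 19 and 327 without peripheral replicate 1, 2 and 3 and 25 without core replicate 2. IRF7, TNFRSF4, TNFAIP3, PLK3, VPS37B, LIME1, TMEM40, ETFB, PDCD1, GZMB and TNFRSF9 alone among those named kept their calls without each library in turn.

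Against normal marrow the Treg libraries of the core had higher TNFRSF4 (3.15 ± 0.39, adjusted p = 1e-04), TNFRSF9 (2.78 ± 0.46), IL1R2 (3.08 ± 0.47) and CTLA4 (1.84 ± 0.45, adjusted p = 0.017). CTLA4 lost its call without normal replicate 4 or core replicate 3 (adjusted p = 0.06 and 0.08), and BATF without core replicate 2 (0.064). PDCD1 (1.11), GZMB (0.80) and LAG3 (0.68) did not pass. Treg effector genes had 4 of 7 higher by both adjustments, with BATF (1.46) (list adjusted p = 2.36e-05, and 0.0393 with an estimated correlation). Calls lost with an estimated correlation were, upward, mature neutrophil (list adjusted p = 5.05e-08, then adjusted p = 0.0833), inflammatory (1.28e-08, then 0.112), T cell markers (5.04e-07, then 0.214), costimulation (9.72e-07, then 0.0833). So were suppressor cell (0.000152, then 0.268), naive and memory (0.000471, then 0.278), hypoxia (0.00102, then 0.278), immediate early (0.00388, then 0.559), cytotoxic effector (0.0122, then 0.212) and inhibitory receptors (0.0146, then 0.306). In these 10 lists 6, 8, 2, 4, 3, 2, 2, 1, 3 and 1 members were higher, and 7, 8, 6, 4, 5, 3, 3, 1, 3 and 1 adjusted over the list alone. Downward went plasma cell markers (5.81e-06, then adjusted p = 0.0858), azurophil granule (0.00145, then 0.357), macrophage markers (0.00181, then 0.409) and endoplasmic reticulum stress (0.0147, then 0.338). In these 4 lists 3, 1, 2 and 3 members were lower, and 6, 7, 5 and 3 adjusted over the list alone. In all 85 genes rose and 214 fell against 104 and 152 in edgeR and 227 and 129 in limma-voom. The median of all genes was -0.11 against -0.01 with RLE scaling. The count was 164, 141 and 151 without normal replicate 1, 2 and 4, 149 without core replicate 2 and 30 among libraries without lung transcripts, with 1 normal library left.

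**Figure D5:**
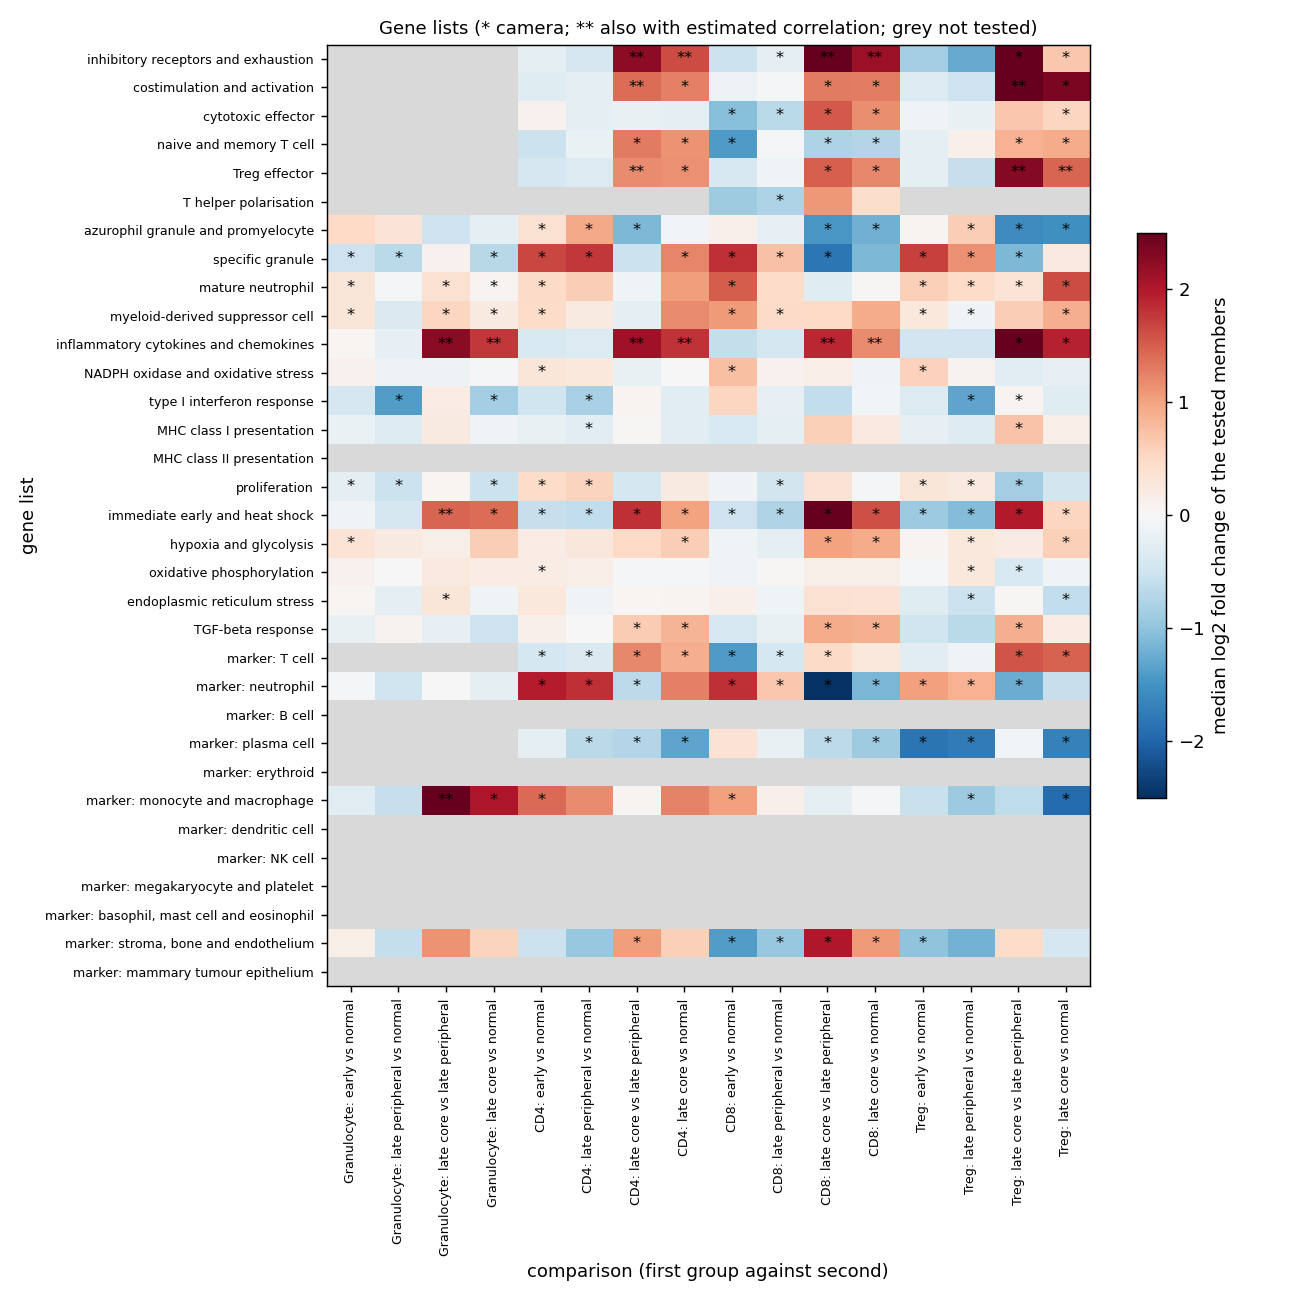
Median log2 fold change of the tested members of each gene list (rows, colour from blue for lower to red for higher) in each comparison (columns). A star marks lists that passed the camera test, a double star those that also passed with an estimated correlation, and grey those with under 4 tested members.

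The 3 T cell populations were compared in 1 model, without animal block, lung covariate or T cell share, to test whether checkpoint gene changes differ. From peripheral marrow to the core PDCD1 rose more in CD8 than in CD4 cells (log2 3.29 ± 0.70, adjusted p = 0.0018). The difference from Treg was 2.62 ± 0.72 (0.013). With 1 read in CD8 and 0 in Treg peripheral libraries, these sizes depend on the offset. LAG3 differed likewise (0.013 and 0.018), as did HAVCR2 from CD4 cells (0.013), with at most 7 HAVCR2 reads in a CD4 library. No difference passed for TIGIT or CTLA4. Of all differences tested 16 passed, 5 with RLE scaling and 6 with edgeR and TMM, and 7 without CD8 peripheral replicate 2 or core replicate 1.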

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

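The tests of lung transcripts over the stages and within populations, of FOXP3 and of the T cell share were chosen after the result was seen; the other splits of the libraries, the marrow stroma test and the lung covariate test were set before their results, after the lung transcripts themselves had been seen.

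Within groups of 4 libraries, 15 of 117 values stood far from the other 3, where chance gives about 5%, or 1 in 20. In 7 of them, all in granulocytes, 1 or 2 reads stand against 0, where any read stands out, so the excess over chance cannot be judged. In CPM these were FOXP3 and ARG1 at 1.55 in normal replicate 2, CD8A and FOXP3 at 0.987 in early replicate 1, IL2RA at 0.612 in early replicate 4 and CD3E at 1.08 and CD4 at 2.15 in peripheral replicate 1, each against 0 in the others. In CD4 libraries they were CD4 at 357 in normal replicate 1 (others 477 to 488), S100A9 at 2000 in normal replicate 2 (292 to 515), CSF3R at 0 in normal replicate 3 (11.2 to 13.2), FOXP3 at 67.7 in early replicate 3 (0 to 11.4) and IL2RA at 43.9 in early replicate 1 (5.7 to 9.67). In CD8 libraries they were CD3E at 235 in normal replicate 3 (167 to 174) and S100A8 at 68600 (4990 to 6690) and CSF3R at 570 (20.8 to 46.3) in early replicate 3.

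Stage effects differed between T cell populations for 4 genes of the inhibitory receptor list (EOMES encodes no receptor). Values are log2 differences with SE and unblocked limma adjusted p. T cell share was not modelled and may shift differences from Treg. From normal to early marrow EOMES gave 1.62 ± 0.47 for CD4 minus CD8 (0.015) and -1.84 ± 0.48 for CD8 minus Treg (0.013), and from normal to peripheral marrow 1.58 ± 0.52 (0.038) and -1.91 ± 0.54 (0.013), where PDCD1 gave 1.78 ± 0.58 for CD4 minus Treg (0.038). From peripheral marrow to the core CD4 minus CD8 was -3.29 ± 0.70 for PDCD1 (0.0018), -3.40 ± 0.90 for LAG3 and -2.43 ± 0.68 for HAVCR2 (0.013 each), and CD8 minus Treg 2.62 ± 0.72 for PDCD1 (0.013), 3.18 ± 0.92 for LAG3 and 2.02 ± 0.60 for EOMES (0.018 each). From normal marrow to the core CD4 minus CD8 was -3.81 ± 0.83 for LAG3 (0.0028), -2.55 ± 0.62 for HAVCR2 (0.0064) and -2.30 ± 0.64 for PDCD1 (0.013), and CD8 minus Treg 3.41 ± 0.64 for PDCD1 (0.00046) and 1.92 ± 0.62 for HAVCR2 (0.038).

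Lung transcripts were in 24 of 55 libraries, and their share differed over the stages (Fisher's exact p = 0.0486), though not within a population (0.899, 0.429, 0.0545 and 0.717). The ratio of SFTPC to MGP reads differed between populations, with medians of 0.907 in granulocytes (0.832 to 1.1), 0.115 in CD4 (0.0688 to 0.287), 0.117 in CD8 (0.0676 to 0.295) and 0.286 in Treg (0.152 to 0.32; permutation p = 1e-05, the smallest that 100000 permutations give). Granulocytes stand apart, but the T cell populations overlap, as core replicate 2 of CD4 and of CD8 lies at the Treg level, so how such RNA entered stays open. Median SFTPC was 7.93 times the highest median of the marrow stroma genes CXCL12, LEPR and BGLAP, but the median deposited value of CXCL12 also stood at 18.3 with and 1.3 without these transcripts, so stromal cells in the gate cannot be told apart from this.

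FOXP3 was low in Treg libraries outside the core, at 14 reads (7.65 to 23.5) against 61.8 expected at the CD4 level, a share of 0.226. This argues against too few reads. Per CD3E read the level was 0.592 of that in CD4 libraries (0.313 to 1.04). Dilution by cells without CD3E cancels in this ratio and may explain a level below CD4 cells, but not the lack of enrichment over them. No biological explanation was tested.

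PDCD1 and CTLA4 rose more than T cell markers in core libraries of CD4 (exact p = 0.0022) and CD8 cells (exact p = 0.015), each the smallest p its splits give, which argues against a larger T cell share as the whole cause there. In Treg the exact p was 0.45, and a larger T cell share may be the cause. With lung transcripts as a covariate the log2 change of PDCD1 from peripheral marrow to the core was 2.35 in CD4, 5.91 in CD8 and 2.92 in Treg. In CD8 all core and no peripheral libraries held these transcripts. Induction of these receptors in the CD4 and CD8 cells of the core is a hypothesis found and tested on the same data.

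Other splits of the same libraries into groups of these sizes were fitted to ask how often they give as many genes. The real split alone, 1 of 35, did so for granulocytes early (182 genes, highest other 99), peripheral (310, 1) and core against normal (478, 1). The same held for CD4 core against normal (172, 1), CD8 early (237, 0), and Treg peripheral (121, 93) and core against normal (299, 112). This is the smallest share that 35 splits can give, and it is not adjusted over the comparisons. It argues against chance in each taken alone, but does not part stage from what goes with it, such as lung transcripts in CD8 early. Chance cannot be excluded for granulocytes core against peripheral (2 of 35, 64 and 163), CD4 core against peripheral (3 of 35, 91 and 194) and Treg early (2 of 35, 8 and 169). In CD4 early and peripheral 0 genes passed, so 35 of 35 splits give as many whatever the cause (highest other 93 and 0), and nothing follows on chance. For Treg core against peripheral marrow 10 splits are too few for a share under 0.05 (73 genes, highest other 48). These splits ignore the mouse that core and peripheral marrow share. Among the splits that part all 3 pairs by animal, 8 in granulocytes and CD4 and 4 in Treg, too few for a share under 0.05, the highest other was 0, 1 and 0 without a block. The splits with 99 in granulocytes early, 93 in CD4 early and 169 and 112 in Treg early and core against normal follow the lung transcripts, a structure of the libraries apart from stage, with which as a covariate the counts were 241, 0, 8 and 277. The split with 93 in Treg peripheral follows them except for peripheral replicate 3. With the covariate that comparison gave 68 genes and CD8 early 8. The split with 163 genes in granulocytes groups peripheral replicates 1 and 2 with core replicate 2, of untested cause. That with 194 in CD4 puts peripheral replicate 2 with the core libraries.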

How the results depend on the processing

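Tests chosen after the data were seen were limma on the scaled values, which gave the reported calls, the 2 other offsets and the 2 lung transcript settings; edgeR with TMM, fixed beforehand, became an alternative to it. No named gene that passed changed sign under any setting; of 329, the call was kept by 281 of 319 with RLE, 317 with DESeq2, 282 of 319 with limma-voom, 283 without a filter, 307 of 315 at a mean of 20 CPM, 278 of 321 with the 2 groups alone, 282 of 319 with edgeR and TMM, 262 and 317 with offsets of 1 and 16, 259 with the lung covariate and 121 of 287 among libraries without lung transcripts. Of 167 lists, 132 and 124 kept their call in these last 2 settings, and at least 147 in the other refits. Where counts differ below, the cause was not tested.

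Genes passing with limma-voom were 885 and 853 for granulocytes early and peripheral, 1, 2, 169 and 373 for CD4 early, peripheral, core against peripheral and core against normal, 5, 40 and 244 for CD8 peripheral, core against peripheral and core against normal, and 64 and 315 for Treg early and peripheral. DESeq2 gave 475 for granulocytes peripheral, 3, 11 and 262 for CD4 early, peripheral and core against normal, 227 and 124 for the CD8 core comparisons, and 23 and 114 for Treg early and core against peripheral. RLE gave 1 for CD4 peripheral, 150 and 119 for CD8 core, 55 and 43 for Treg peripheral and core against peripheral and 5 differences between populations; edgeR with TMM gave 1, 155, 116, 75, 39 and 6. No filter gave 205 for granulocytes peripheral and 114, 136 and 146 for CD8 early and core, and a mean of 20 CPM 37 for CD8 core against peripheral. The 2 groups alone gave 588 for granulocytes peripheral, 5 and 329 for CD4 peripheral and core against normal, 267 and 221 for CD8 core, and 66, 186 and 9 for Treg early, peripheral and core against peripheral. An offset of 1 gave 50 for CD4 core against peripheral, 20 and 31 for CD8 core and 5, 46 and 34 for Treg early, peripheral and core against peripheral; 16 gave 2 for CD4 peripheral, 121 and 92 for CD8 core and 18 for Treg early. The lung covariate gave 8, 10 and 34 for CD8 early, core against peripheral and core against normal, and 68 and 132 for Treg peripheral and core against peripheral. Libraries without lung transcripts gave 575 for granulocytes core against peripheral, 0 and 0 for CD4 core, 0 for CD8 early, and 6, 149 and 30 for Treg peripheral, core against peripheral and core against normal. Here 1 library is left in the core of granulocytes and CD4 and in normal CD4 and Treg, assumed to vary like the other groups. For CD8 core this last setting could not be run, as no core library is left. Of list tests 17 passed with an estimated correlation and 71 with fry.

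With the animal as a replicate block 216 genes passed for Treg core against peripheral marrow, and the count was 62 in granulocytes, 71 in CD4 and 48 in CD8, against 64, 91 and 62. Of 106 named genes that passed 12, and of the lists 1, lost their call, each named with its comparison; it changed no other call of a named gene that passed or of a list that passed, while the lists that passed numbered 169 and 168 with the granulocyte and Treg block, against 167. Elsewhere the samples share only a number; with the title number as a replicate block 2 and 3 genes passed for CD4 early and peripheral, 95 for CD8 core against peripheral, and 40 and 118 for Treg early and core against peripheral. By title number every library correlated best with its own number in the Treg core against peripheral comparison (3 of 3) and in no other with 3 or more pairs.

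Leaving out each library gave 93 to 213, 146 to 393, 51 to 135 and 266 to 531 genes in granulocytes (early, peripheral, core against peripheral, core against normal), 0 to 3, 0 to 7, 20 to 198 and 34 to 264 in CD4, 59 to 345, 0 to 0, 7 to 108 and 11 to 82 in CD8, and 1 to 25, 22 to 187, 19 to 327 and 141 to 427 in Treg, 163 to 177 lists and 7 to 18 differences. Where it leaves 1 CD8 library in a group, that lone library is assumed to vary like the other groups. Log2 values of genes that had not passed and changed sign ran, in granulocytes early, from -0.26 to 0.18 for S100A8 and -0.76 to 0.07 for S100A9, and for core against normal from -0.20 to 0.25 for S100A8, -0.31 to 0.48 for S100A9 and -0.59 to 0.04 for CXCR2. In CD4 early they ran from -0.21 to 0.30 for TIGIT, -0.39 to 0.02 for CTLA4 and -0.26 to 0.08 for LAG3, in CD4 peripheral from -0.18 to 0.16 for PDCD1 and -0.62 to 0.05 for FOXP3, and in CD4 core against peripheral from -0.84 to 0.13 for LAG3. HAVCR2 ran from -0.07 to 0.31 in CD8 early and from -0.07 to 0.33 in CD8 peripheral, where LAG3 ran from -1.37 to 0.41 and GZMB from -1.11 to 0.59. LAG3 in Treg core against peripheral ran from -0.69 to 0.60.

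Values that reversed had not passed, lists aside. S100A8 in granulocytes early was 0.03 with RLE, DESeq2 and TMM, and for core against normal 0.04, 0.03 and 0.02 with these, 0.16 with limma-voom and 0.70 without lung libraries, where S100A9 was -0.09 with the title block and -0.03 with the lung covariate. PDCD1 in CD4 peripheral was 0.25 with limma-voom, LAG3 in CD4 core against peripheral 0.13 with the animal block and TIGIT in CD4 early -0.28 without lung libraries. CTLA4 and HAVCR2 in CD8 peripheral were -0.06 and -0.04 with the title block. LAG3 in Treg core against peripheral was 0.34, 0.31 and 0.35 with RLE, DESeq2 and TMM and 0.02 with an offset of 16, and PDCD1 in Treg early 0.12 without lung libraries. Lists whose test pointed the other way had lost their call, except where a p is given; medians were, with the lung covariate, 0.37 for neutrophil markers in CD4 core against peripheral, -0.03 for immediate early genes in CD8 early, 0.07, -0.15 and 0.06 for specific granule, neutrophil and stromal genes in CD8 peripheral, and -0.37 and 0.33 for azurophil and specific granule genes in CD8 core against peripheral. Without lung libraries they were 0.73 for the first of these (adjusted p = 0.036), the same -0.03, 0.07, -0.15 and 0.06 in CD8, 0.28 and 0.11 for immediate early and stromal genes in Treg early and -0.01 for immediate early genes in Treg peripheral.

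Depth limits genes with few reads: the early CD8 libraries hold 43224 to 144170 reads, and TIGIT, FOXP3 and IFNG in Treg libraries had at most 11 reads in any library and were not tested.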

Other observations

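The epithelial keratin genes KRT8 and KRT18, which mammary tumour cells express, stood at a mean of 24.8 and 25.4 CPM in CD4 and 25.1 and 76.9 CPM in Treg libraries of the core (2.4 and 12.8 CPM in normal marrow), at 8.8 and 19.7 CPM in its CD8 libraries (0.515 and 6.97 CPM in normal marrow) and at 11.1 and 11.6 CPM in its granulocytes, against 0 and 2.03 CPM in granulocytes and 0 and 4.03 CPM in CD4 cells of normal marrow. Libraries of a group differed: KRT18 ran from 3.95 to 59.8 CPM in CD4 and from 27.7 to 155 CPM in Treg libraries of the core, and KRT8 from 0 to 55.5 CPM in the latter. Outside the core KRT18 had a mean of 14.6 CPM in CD4 and 16.1 CPM in Treg libraries of peripheral marrow, and KRT8 of 8.09 CPM in early CD8 libraries.

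Among abundant genes GAPDH varied most between libraries of the same group, with a within-group SD of 3.37 on the log2 scale in granulocytes (39.9 to 5240 CPM), where the median gene had 0.32, and of 2.96 in Treg libraries (15.1 to 4700 CPM). In CD4 libraries RPS2 had the highest SD, at 2.89 (5.7 to 3280 CPM).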
